A study of Oncorhynchus tshawytscha with 17 samples.

How the data were processed

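The counts analysed here are the featureCounts table that the authors deposited. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.38, aligned with HISAT2 and counted with featureCounts. The versions of HISAT2 and featureCounts, the genome build, the strandedness and the handling of reads that map to several places are not given in the sources used here. The labels describe total RNA extracted with TRIzol and paired-end NovaSeq sequencing, after 10 days of treatment and euthanasia with an overdose of clove oil. Reads were not realigned.

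Depth is the sum of counts over named genes. In M (1e6) it was 56.7 for ctl12A, 41.4 for ctl12B, 49.5 for ctl12C, 43.8 for ctl35A, 47.6 for ctl35B and 38.1 for ctl35C. It was 59.4 for abx67A, 52.8 for abx67B, 39.9 for abx67C, 43.6 for abx91A and 58.6 for abx91B. It was 47.2 for pro115A, 28.6 for pro115B, 42.9 for pro115C, 61.1 for pro139A, 38.2 for pro139B and 57.5 for pro139C. Of 42555 entries in the table, 42554 carry a gene identifier and 1 has none. The unnamed entry spans mitochondrial rRNA and tRNA positions. It was left out of the tests and held 0.155 to 0.523% of counts. Its share did not differ between groups by exact permutation (p = 0.472 for antibiotic and p = 0.963 for probiotic fish against controls, p = 0.500 between the treatments).

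Gene symbols came from the table for 4401 identifiers and, for LOC identifiers, from a reference table of assembly Otsh_v2.0. That table was used for names only. It holds 30285 of 38153 LOC identifiers and gives a symbol to 6084. Salmonid genomes hold many recent gene copies, so a symbol may stand for 1 of several copies, and lists hold only the copies that have a symbol. Identifiers without a symbol are in no list. A list symbol was also matched with a short suffix, so cp brought cpd, not a liver marker, into the liver list and its counts. Coordinates are those of the deposited table.

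A gene was tested where edgeR's filterByExpr kept it, which left 30221 genes. Normalisation was TMM. The test was edgeR's robust quasi-likelihood F-test, which is 2-sided, in a fit of all 17 libraries with group as the only factor, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold change. Log2 CPM used a prior count of 2. These choices, the groups and the gene lists were fixed before the data were examined. Of 37 lists, 35 had the 5 tested members required. The list of mitochondrially encoded genes and that of antimicrobial peptides and lectins were left out, with 0 and 4 tested members. Lists were tested with limma camera on voom values at a preset correlation of 0.01, 2-sided, and adjusted over the lists of a comparison. The same lists were tested with an estimated correlation, whose median was 0.303 for antibiotic and 0.302 for probiotic fish against controls, and with fry. Neither called a list in any comparison. List scores were compared by 2-sided exact permutation.

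Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. DESeq2 gave no adjusted p to 208 genes in each comparison with control and to 1380 genes between the treatments. Of its calls, 11 of 26, 14 of 34 and 10 of 23 had a range of over 3 log2 units among fish of a group.

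By the rule fixed for naming genes, the 10 genes with the smallest p are named as not passing where under 5 are called, and the member of smallest p of a list and the most abundant member of a list of another tissue may be named too. Genes named beyond that rule were chosen after the values were seen. These are further members of lists called by camera, genes with a symbol called by DESeq2, members that passed when adjusted over the list alone, and oocyte genes.

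The pipeline was tested on simulated counts with the group sizes and spread of the data, with 100 genes changed 2-fold and 100 changed 4-fold among 30221. Changed genes were drawn only from those with a mean of at least 1 CPM, so recovery of scarcer genes was not measured. In antibiotic versus control edgeR recovered 49% of 2-fold and 92% of 4-fold changes, with 6 unchanged genes called. In probiotic versus control it recovered 51% and 93%, with 6 unchanged genes called. In antibiotic versus probiotic it recovered 49% and 93%, with 5 unchanged genes called. DESeq2 recovered 65%, 71% and 67% of 2-fold and 95%, 97% and 95% of 4-fold changes, with 40, 39 and 41 unchanged genes called. Voom recovered 48%, 53% and 51% of 2-fold and 94%, 88% and 90% of 4-fold changes. The mitochondrial ribosome list, the largest with 54 tested members, was moved by a log2 of 0.5. It was called in each comparison, with medians of 0.45, 0.50 and 0.51. Of the other lists 0, 3 and 0 were called. Simulated genes varied independently, whereas the median estimated correlation within lists of the data was 0.302 to 0.303. The simulation therefore does not measure how often camera calls unmoved lists in these data.

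Alternatives were other normalisations (RLE, upper quartile), no filter, a mean CPM of at least 1, leaving out the 20 most abundant genes, fits of only the 2 groups, DESeq2, voom, quality weights, title number as a random block, counts summed per title number, 1 surrogate variable, the smooth muscle score as a covariate, a minimum absolute log2 fold change of 1, a prior count of 0.5, medians for means, and each fish left out in turn. Added after values were seen were leaving out abx67C, abx91B, pro139B and pro139C, in which genes of other organs were high (abx67B and pro115A, with 11 and 10 of 18 liver genes above all controls, were kept), leaving out ctl12A and pro139A, the index plate column as a covariate, and each fish left out in turn for title numbers and the shared response. The index plate column was read from the index names in the library titles. The name for abx67C is irregular and was read as column 9, and the labels do not say that a column is a batch of preparation. Each group holds 2 title numbers, which may mark a shared tank, and the labels do not say. If they do, fish are not independent and p-values measure only the spread between these fish.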

Results

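The data were RNA sequencing counts from the hindgut of 17 Chinook salmon (Oncorhynchus tshawytscha), a Pacific salmonid. The hindgut is the last part of the intestine, where enterocytes take up and digest whole protein, and the labels describe the material as hindgut epithelium and the fish as diploid. The fish fell into 3 groups: 6 healthy controls, 5 fish that received antibiotics for 10 days and 6 fish that received probiotics for 10 days. The antibiotics, the probiotic strains and the doses are not given in the sources used here. The series sets out to find host genes whose expression differs with the treatment of the gut microbiota. Fish are named here by the number and letter in their titles, after ctl for controls, abx for antibiotic and pro for probiotic fish. Controls are ctl12A, ctl12B, ctl12C, ctl35A, ctl35B and ctl35C, antibiotic fish are abx67A, abx67B, abx67C, abx91A and abx91B, and probiotic fish are pro115A, pro115B, pro115C, pro139A, pro139B and pro139C. Counts assigned to named genes came to 46.2 ± 6.58 M (1e6) per library in controls (SD, n = 6), 50.9 ± 8.81 M in antibiotic fish (SD, n = 5) and 45.9 ± 12 M in probiotic fish (SD, n = 6). Single libraries ranged from 28.6 M in probiotic pro115B to 61.1 M in probiotic pro139A. Of 42554 named genes, 30221 were abundant enough to be tested, and 8792 of these had a gene symbol.

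Hindgut profiles of the 3 groups were intermixed. The first principal component of the 1000 most variable genes held 16% of the variance, and group accounted for 17.4% of it (permutation p = 0.267). The second component held 10%, with 7.61% accounted for by group (permutation p = 0.579). Across genes, the mean correlation of log2 CPM between fish of one group was 0.950, against 0.949 between fish of different groups (one-sided permutation p = 0.180). Genes are not independent replicates, and the permutation moved whole fish.

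**Figure D1:**
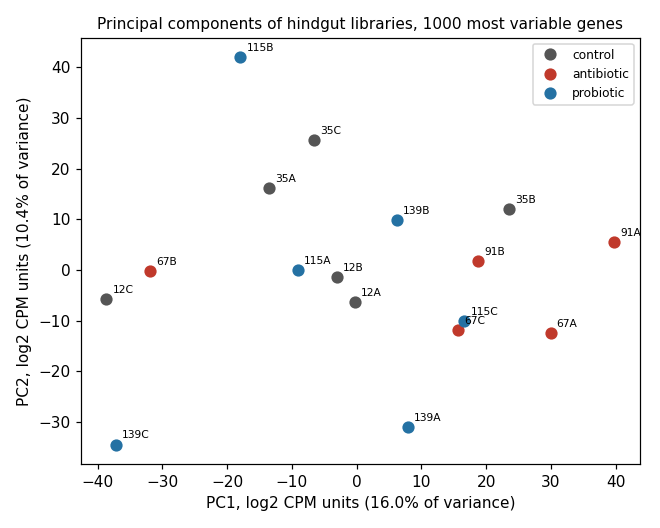
Principal component scores of the 17 hindgut libraries from the 1000 most variable genes, in log2 CPM units, with each point a fish coloured by group. The first component (16% of variance) and the second (10%) both intermix control, antibiotic and probiotic fish.

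The first comparison asked which hindgut genes differed between fish given antibiotics and controls. Genes of protein synthesis and of cell division lay on the higher side in antibiotic fish, and genes of the lysosomal enterocyte and of red blood cells on the lower side. Of 54 mitochondrial ribosome genes, which build the ribosome inside mitochondria, 47 had a fold change above 1, with a median of 1.12-fold (log2 0.16). Of 40 cytosolic ribosomal protein genes, 36 were above 1, with a median of 1.09-fold (log2 0.12). Of 23 cell cycle genes, 19 were above 1, with a median of 1.49-fold (log2 0.57). These lists passed camera, a test of whether a list ranks apart from all other genes, at adjusted p = 0.000409, 0.00784 and 0.00784. With an estimated correlation in place of the preset 0.01, none of them passed (adjusted p = 0.857 with an estimated correlation for each).

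On the lower side, 16 of 20 genes of the endocytic and lysosomal enterocyte list were below the controls, with a median log2 fold change of -0.14 (camera adjusted p = 0.0319, and adjusted p = 0.857 with an estimated correlation). Its member with the smallest p was hexb, a lysosomal enzyme that removes terminal hexosamines. It stood at 4968 ± 477 CPM in antibiotic fish (SD, n = 5) and 6500 ± 968 CPM in controls (SD, n = 6), and all 5 antibiotic fish lay below all controls (log2 fold change -0.39 ± 0.12 SE, edgeR adjusted p = 0.734). Of 7 erythrocyte genes, 6 were lower, with a median log2 fold change of -0.48 (camera adjusted p = 0.0270, and adjusted p = 0.857 with an estimated correlation). Among them slc4a1a, the anion exchanger of red cells, averaged 8.09 ± 2.64 CPM (SD, n = 5) against 16.4 ± 13.7 CPM in controls (SD, n = 6), while hemgn, the most abundant member, averaged 25.1 ± 5.47 and 25.7 ± 8.98 CPM. The call ended with any of 5 fish left out singly and with the plate column (median -0.37, camera adjusted p = 0.132), and over all alternatives the median ranged from -0.84 to -0.21.

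In the cell cycle and mitochondrial ribosome lists the member with the smallest p went against the list. The folate enzyme gene dhfr, of the cell cycle list, had a log2 fold change of -4.78 that rested on control ctl35C at 35.1 CPM, with at most 0.379 CPM in any other fish. The mitochondrial ribosome gene mrpl48 had one of -2.49, with 0.262 ± 0.0748 against 1.49 ± 2.46 CPM and a control at 6.27 CPM. The proliferation marker mki67 averaged 112 ± 62.4 CPM in antibiotic fish (SD, n = 5) and 57.5 ± 34.1 CPM in controls (SD, n = 6), with edgeR adjusted p = 0.816. The mitotic kinase aurka averaged 16.1 ± 8.40 and 8.17 ± 5.27 CPM, and the mitochondrial ribosome gene mrpl2 averaged 32.5 ± 4.50 and 24.2 ± 4.72 CPM. No member of the 5 lists passed edgeR's test over all genes, and none passed when adjusted over the list alone. At an unadjusted p under 0.05 there were 3 members of the mitochondrial ribosome list, 2 of the erythrocyte list and 1 each of the cell cycle, cytosolic ribosomal and lysosomal lists. Outside these 5 lists, b3gnt7, a glycosyltransferase of the mucus and goblet cell list, passed when adjusted over the list alone, at 5.25 ± 1.43 CPM against 3.37 ± 0.711 CPM. That list did not pass as a whole (camera adjusted p = 0.469), nor did the lists of B cells (0.236), of T cells (0.921) or of pattern recognition and NF-kB signalling (0.979).

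Liver genes also lay on the higher side in antibiotic fish. Of 18 liver genes, 16 were higher, with a median log2 fold change of 0.55 (camera adjusted p = 0.0894, and adjusted p = 0.857 with an estimated correlation). Over all genes 0 members passed in edgeR, and 5 passed when adjusted over the list alone: fgg, hpxb, f9, fetub and plg. The plasma protein gene fetub averaged 7.14 ± 11.8 CPM (SD, n = 5) against 0.724 ± 0.355 CPM in controls (SD, n = 6), with 27.9 CPM in fish abx67C. The most abundant member, cpd (71.9 ± 4.39 against 74.4 ± 7.54 CPM), is not a liver marker. It entered only because the list symbol cp was matched with an optional suffix, and hpdl may have entered in the same way. The 18 genes include both. Levels of f9 rested on abx67B alone (84.7 CPM, with at most 2.17 CPM in the other antibiotic fish). Those of hpxb and plg rested on abx67C (8.90 and 4.05 CPM) and abx67B (1.65 and 0.470 CPM), and the other antibiotic fish did not exceed the highest control. The liver score of antibiotic fish, the mean log2 CPM over members, was 0.46 ± 1.49 against -0.29 ± 0.42 in controls (exact permutation p = 0.320). Scores of smooth muscle were 4.53 ± 0.50 and 4.82 ± 0.61 (exact permutation p = 0.368), and those of exocrine pancreas 2.23 ± 0.80 and 2.96 ± 1.04 (exact permutation p = 0.247).

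No single gene passed edgeR's quasi-likelihood test between antibiotic fish and controls (0 of 30221). At an unadjusted p under 0.05 there were 1877 genes, 1111 of them higher, where 1511 were expected by chance. In fits of only these 2 groups, 10 of 50 splits of the libraries, the real one included, had as many as the real division. DESeq2 called 26 genes, 14 of them higher, and limma-voom called 0. The smallest edgeR p belonged to wash1, a subunit of the complex that builds actin on endosomes. Its transcripts averaged 35.7 ± 2.70 CPM in antibiotic fish (SD, n = 5) and 64.0 ± 15.1 CPM in controls (SD, n = 6), and all 5 antibiotic fish lay below all controls (log2 fold change -0.84 ± 0.16 SE, edgeR adjusted p = 0.645, DESeq2 adjusted p = 0.00477). In the deposited table wash1 lies on the plus strand of sequence NC_037115.1, from 31522460 to 31528039, on a genome build not given in the sources used here. Next came LOC112241821 (15.4 ± 4.67 against 7.05 ± 1.5 CPM) and LOC112241820 (11.8 ± 3.71 against 4.56 ± 1.31 CPM), which have no gene symbol in the reference table. Both were higher in all 5 antibiotic fish than in all controls, at log2 fold changes of 1.13 ± 0.22 and 1.37 ± 0.27 (SE; edgeR adjusted p = 0.645, DESeq2 adjusted p = 0.00618). They are neighbours on the plus strand of scaffold NW_020131978.1, at 27697 to 34377 for LOC112241820 and 34479 to 37217 for LOC112241821.

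The rest of the 10 genes with the smallest p did not pass in edgeR either. LOC112249106, LOC112259970, ubr4 and LOC112248188 were higher by log2 0.77, 3.48, 2.75 and 5.54. LOC112234113, LOC112255867 and LOC112226994 had log2 fold changes of -4.63, -1.08 and -0.81. The ubiquitin ligase gene ubr4 averaged 7.23 ± 4.04 CPM against 1.07 ± 0.499 CPM, with antibiotic fish abx91A at 1.02 CPM inside the control range. LOC112248188 averaged 8.76 ± 11.7 CPM, and 2 of 5 antibiotic fish lay above all controls. Among genes called by DESeq2 alone, treh, the brush border enzyme that splits trehalose, averaged 183 ± 25.7 CPM (SD, n = 5) against 261 ± 35 CPM in controls (SD, n = 6). It was below all controls in 5 of 5 fish (DESeq2 adjusted p = 0.0185, edgeR adjusted p = 0.698). The cilium gene cfap58 averaged 3.14 ± 0.989 against 10 ± 6.2 CPM, xrra1 32.7 ± 3.71 against 68.4 ± 24.1 CPM, and nppb, a natriuretic peptide gene, 0.315 ± 0.170 against 0.944 ± 0.159 CPM.

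In 146 genes (0.483% of those tested) the antibiotic and control fish did not overlap, where chance gives 0.433%. Of 32 alternatives, 6 each ended the camera calls of the cell cycle and mitochondrial ribosome lists, 7 that of the cytosolic ribosomal list and 9 each those of the lysosomal and erythrocyte lists, and no list score passed exact permutation (smallest adjusted p = 0.669). With the smooth muscle score as a covariate the cell cycle median was 0.34 (camera adjusted p = 0.136) and the mitochondrial ribosome median 0.051 (0.316), with the plate column read from the library titles they were 0.21 (0.502) and 0.018 (0.811) while the lysosomal and cytosolic ribosomal medians grew to -0.27 and 0.20 (8.66e-06 and 5.00e-09), and wash1 passed edgeR (adjusted p = 0.0460). Without ctl12A and pro139A the cytosolic ribosomal median fell to 0.046 and its call ended (camera adjusted p = 0.301). The lysosomal call ended then too, and also without abx67C, abx91B, pro139B and pro139C (median -0.084, camera adjusted p = 0.157).

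**Figure D2:**
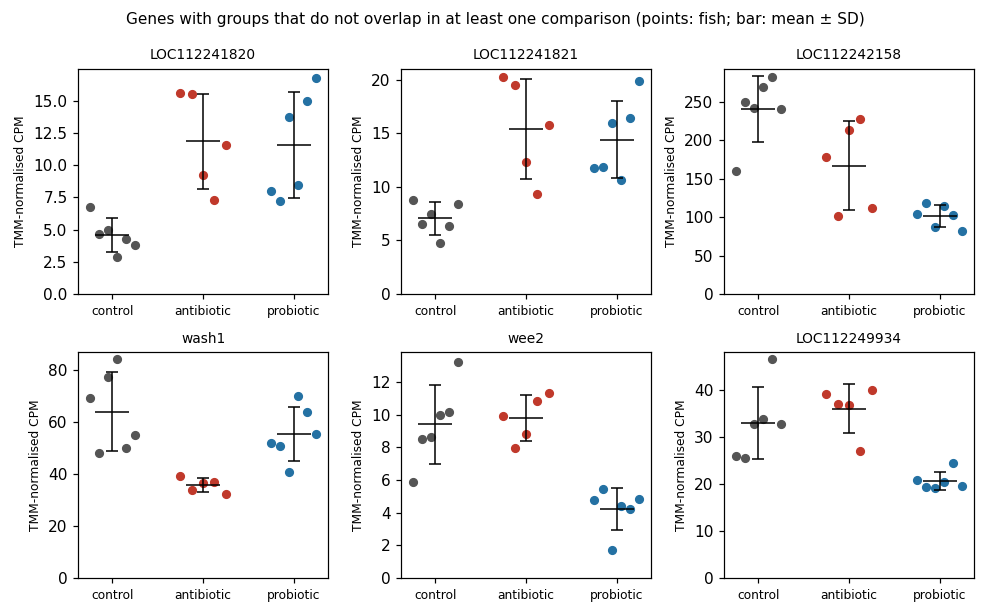
TMM-normalised CPM of 6 genes in control (n = 6), antibiotic (n = 5) and probiotic fish (n = 6), with points for fish and bars for mean ± SD. LOC112241820 and LOC112241821 were higher in all treated fish than in all controls, wash1 was lowest on average in the antibiotic fish, and LOC112242158, wee2 and LOC112249934 were lowest on average in the probiotic fish. The genes were chosen because groups did not overlap in at least 1 comparison, and both treatments are set against the same controls.

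The second comparison asked which hindgut genes differed between fish given probiotics and controls. Mitochondrial ribosome, heat shock, sterol synthesis and cell cycle genes lay on the higher side in probiotic fish. Of 54 mitochondrial ribosome genes, 49 were higher, with a median of 1.19-fold (log2 0.25, camera adjusted p = 9.96e-11). Of 26 heat shock and unfolded protein response genes, which refold or clear misfolded proteins, 22 were higher, with a median of 1.34-fold (log2 0.43, camera adjusted p = 5.49e-05). Of 16 cholesterol and sterol synthesis genes, 15 were higher, with a median of 1.29-fold (log2 0.37, camera adjusted p = 0.00428). Of 23 cell cycle genes, 21 were higher, with a median of 1.44-fold (log2 0.53, camera adjusted p = 0.00477). With an estimated correlation none of the 4 lists passed (adjusted p = 0.887 with an estimated correlation for each).

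Examples from these lists did not pass on their own. The chaperone gene hspa8 averaged 14.9 ± 7.60 CPM in probiotic fish (SD, n = 6) and 7.68 ± 2.71 CPM in controls (SD, n = 6), with edgeR adjusted p = 0.446. The endoplasmic reticulum chaperone gene hyou1 averaged 73.5 ± 27.3 against 33.2 ± 18.9 CPM, and 4 of 6 probiotic fish lay above all controls. The sterol enzyme gene fdps averaged 43.4 ± 18.4 against 27.8 ± 6.74 CPM. The cell cycle member with the smallest p was again dhfr, which went against the list (log2 fold change -4.73) through control ctl35C at 35.1 CPM. The transcription factor gene e2f1, next by p, averaged 6.21 ± 2.43 against 3.51 ± 1.13 CPM. Among mitochondrial ribosome genes, mrpl43 averaged 13.3 ± 2.60 against 9.51 ± 2.03 CPM and mrps11 averaged 7.03 ± 1.43 against 4.66 ± 0.852 CPM. At an unadjusted p under 0.05 there were 13 mitochondrial ribosome, 9 heat shock, 6 cell cycle and 4 sterol genes. Over all genes 0 members passed in edgeR, and 0 when adjusted over the list alone.

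The lower side held 5 lists. Smooth muscle genes were below controls in 9 of 9 members, with a median log2 fold change of -0.48 (camera adjusted p = 0.00546, and adjusted p = 0.887 with an estimated correlation). The calponin gene cnn1b, a smooth muscle marker, averaged 336 ± 111 CPM (SD, n = 6) against 576 ± 274 CPM in controls (SD, n = 6), and tpm2, the most abundant member, 1123 ± 260 against 1444 ± 500 CPM. The smooth muscle score was 4.32 ± 0.45 against 4.82 ± 0.61, within the spread of fish (exact permutation p = 0.139). Without abx67C, abx91B, pro139B and pro139C, in which genes of other organs were high, the median was -0.25 and camera no longer called the list (adjusted p = 0.0861), the heat shock median shrank to 0.24 (0.00764) and the lysosomal median grew to -0.29 (0.000132). All 12 circadian clock genes were lower, with a median of -0.27 (camera adjusted p = 0.0103, and adjusted p = 0.887 with an estimated correlation). The clock repressor gene nr1d2a averaged 30.1 ± 8.92 against 42.9 ± 12 CPM. Endocytic and lysosomal enterocyte genes were lower in 15 of 20 members, with a median of -0.14 (camera adjusted p = 0.00546, and adjusted p = 0.887 with an estimated correlation). Its lysosomal protease gene ctsh averaged 3029 ± 745 against 4394 ± 1062 CPM. For hexb, 5192 ± 446 CPM stood against 6500 ± 968 CPM, and 5 of 6 probiotic fish lay below all controls.

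Antigen presentation genes were lower in 6 of 7 members, with a median log2 fold change of -0.35 (camera adjusted p = 0.0270, and adjusted p = 0.887 with an estimated correlation). The costimulatory receptor gene cd40, with the smallest p, averaged 28.6 ± 6.04 CPM in probiotic fish and 35.9 ± 5.03 CPM in controls. Without ctl12A and pro139A the median was -0.19 (camera adjusted p = 0.204), and 4 of the fish left out singly ended the call. Immediate early genes, which respond within minutes to stimulation or handling, were lower in 19 of 25 members, with a median of -0.12 (camera adjusted p = 0.0468, and adjusted p = 0.887 with an estimated correlation). That call ended in 20 of 32 alternatives, 10 of them with a single fish left out, with medians from -0.28 to -0.052. The stress transcription factor gene atf3 averaged 74.6 ± 32.3 against 114 ± 26.7 CPM. By exact permutation of list scores, antigen presentation (p = 0.0346) and heat shock (p = 0.0455) had the smallest values, and neither passed over the 35 lists (smallest adjusted p = 0.485). Outside the 9 lists, abcc3, an organic anion exporter of the bile acid list, passed when adjusted over the list alone, at 1.39 ± 0.795 against 0.375 ± 0.196 CPM. That list did not pass as a whole (camera adjusted p = 0.771), nor did the lists of complement (0.460), of inflammatory cytokines and chemokines (0.410) or of the absorptive enterocyte (0.918).

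**Figure D3:**
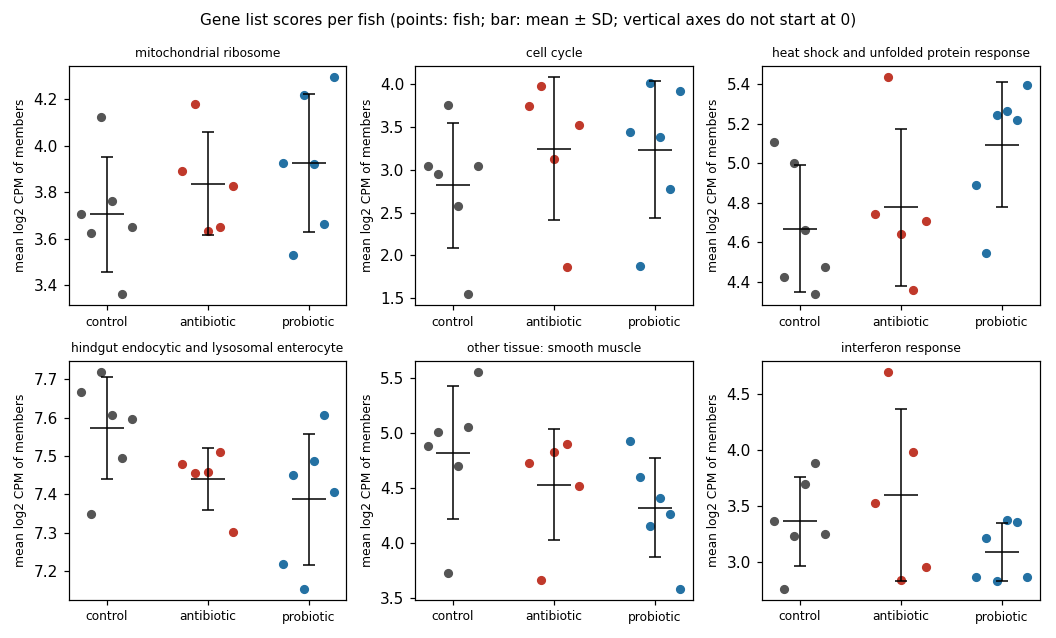
Scores of 6 gene lists in control (n = 6), antibiotic (n = 5) and probiotic fish (n = 6), each the mean log2 CPM of the list's tested members, with points for fish and bars for mean ± SD. Vertical axes do not start at 0, and the groups overlap in each list shown.

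No single gene passed edgeR between probiotic fish and controls (0 of 30221). At an unadjusted p under 0.05 there were 2935 genes, 1598 of them higher, where 1511 were expected by chance. In fits of only these 2 groups, 5 of 50 splits of the libraries, the real one included, had as many as the real division. DESeq2 called 34 genes, 15 of them higher, and limma-voom called 0. The smallest p in any comparison belonged to LOC112242158, a protein-coding gene with no symbol, on the minus strand of scaffold NW_020132678.1 from 12018 to 19669. It averaged 101 ± 14.4 CPM in probiotic fish (SD, n = 6) and 240 ± 42.7 CPM in controls (SD, n = 6), and all 6 probiotic fish lay below all controls (log2 fold change -1.25 ± 0.19 SE, edgeR adjusted p = 0.166, DESeq2 adjusted p = 2.16e-05). The control fish ctl12A, at 160 CPM, was the lowest of its group. With only the 2 groups compared in the fit, LOC112242158 passed edgeR (adjusted p = 0.0214).

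Next by p was frmd4bb, a FERM domain gene, at 24.2 ± 5.86 against 44.9 ± 7.81 CPM, with all 6 probiotic fish below all controls (log2 fold change -0.89 ± 0.17 SE, edgeR adjusted p = 0.446, DESeq2 adjusted p = 0.00438). The kinase gene wee2, whose product holds back entry into division, averaged 4.23 ± 1.31 against 9.40 ± 2.42 CPM, again lower in 6 of 6 fish (log2 fold change -1.15 ± 0.23 SE, edgeR adjusted p = 0.446). It is also on the list of oocyte genes used further below, although it was counted in every fish. The arginine methyltransferase gene prmt3 averaged 11.7 ± 2.43 against 7.36 ± 0.788 CPM, above all controls in 6 of 6 fish (log2 fold change 0.67 ± 0.14 SE, edgeR adjusted p = 0.446). LOC112241820 (11.5 ± 4.12 against 4.56 ± 1.31 CPM) and LOC112241821 (14.4 ± 3.59 against 7.05 ± 1.5 CPM) lay above all controls in all 6 probiotic fish. LOC112248608 and LOC112249934 both had log2 fold changes of -0.68, LOC112261503 had 0.90 and LOC112234485 had 5.6. Fish differed widely in LOC112234485, from 0.0361 to 15.5 CPM within the probiotic group.

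Genes with a symbol called by DESeq2 alone included eif6, a factor of ribosome assembly, at 29.2 ± 3.20 CPM (SD, n = 6) against 21 ± 2.37 CPM in controls (SD, n = 6), higher in 6 of 6 fish (DESeq2 adjusted p = 0.0443). Endosomal and membrane genes among them were rabep2 (36.5 ± 6.01 against 57.6 ± 10.0 CPM), sidt2 (64.8 ± 14.1 against 108 ± 20.1 CPM) and tmem38b (133 ± 11 against 188 ± 13 CPM). The pentose phosphate enzyme gene pgd averaged 8.40 ± 12 against 0.535 ± 0.252 CPM, with 4 of 6 fish above all controls. In 88 genes (0.291%) the groups did not overlap, where chance gives 0.216%. With the smooth muscle score as a covariate the medians were -0.029 for the cell cycle (camera adjusted p = 0.636), 0.010 for sterol synthesis (0.859), -0.11 for the circadian clock (0.149) and -0.15 for immediate early genes (0.0991), so that only this last one did not shrink as its call ended. The mitochondrial ribosome and heat shock lists passed with medians of 0.093 and 0.11 (camera adjusted p = 0.0241 each), and with the plate column the lysosomal and antigen presentation calls ended at medians hardly changed, of -0.12 and -0.33 (0.0782 each).

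The third comparison set the antibiotic fish against the probiotic fish directly. Immediate early, interferon and cytosolic ribosomal protein genes lay on the higher side in antibiotic fish, and heat shock and mitochondrial ribosome genes on the lower side, in small shifts that depended on the test. Of 25 immediate early genes 23 were higher, with a median of 1.33-fold (log2 0.41, camera adjusted p = 0.000141). Of 10 interferon response genes, which act against viruses, 9 were higher, with a median of 1.34-fold (log2 0.42, camera adjusted p = 0.00646). Of 40 cytosolic ribosomal protein genes 37 were higher, with a median of 1.07-fold (log2 0.10, camera adjusted p = 0.0130). Of 26 heat shock genes 22 were lower, with a median log2 fold change of -0.31 (camera adjusted p = 0.000187), and of 54 mitochondrial ribosome genes 41 were lower, with a median of -0.11 (camera adjusted p = 0.00498). Of 32 alternatives, 8 ended the mitochondrial ribosome call, 3 of them with a single fish left out. The cytosolic ribosomal call ended in 10, 4 of them with a single fish left out. With an estimated correlation none of these 5 lists passed (adjusted p = 0.940 with an estimated correlation for each), and no list score passed exact permutation (smallest adjusted p = 0.825).

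The interferon list carried 5 members that passed when adjusted over the list alone (rsad2, dhx58, stat1b, ifit8 and cmpk2) and 0 over all genes in edgeR, where 5 had an unadjusted p under 0.05. The antiviral gene rsad2 averaged 6.15 ± 11.8 CPM in antibiotic fish (SD, n = 5) and 0.491 ± 0.390 CPM in probiotic fish (SD, n = 6), with 2 of 5 antibiotic fish above all probiotic fish and a single fish at 27.2 CPM. The interferon median was 0.24 without abx67B (camera adjusted p = 0.296) and 0.95 without abx67C, abx91B, pro139B and pro139C (1.46e-11), and with the plate column it stayed at 0.43 as the call ended (0.127). The RNA sensor gene dhx58 averaged 47.0 ± 16.7 against 26.6 ± 10.9 CPM, and stat1b, a transducer of interferon signals, 23.0 ± 8.63 against 15.1 ± 2.67 CPM. Among immediate early genes, dusp5 averaged 15.5 ± 11.2 against 7.29 ± 1.45 CPM and egr1 92.9 ± 120 against 37.5 ± 14.4 CPM. Among heat shock genes, sel1l averaged 62.5 ± 13.9 against 89.6 ± 22.4 CPM and hyou1 36.9 ± 24.6 against 73.5 ± 27.3 CPM. Lists of other tissues moved further without passing. All 6 exocrine pancreas genes were lower (median log2 fold change -0.97, camera adjusted p = 0.0681, and adjusted p = 0.940 with an estimated correlation), 4 of them at an unadjusted p under 0.05. This leaned on pro139C, with 240 CPM of ela2 and 295 CPM of cpb1, against at most 43.8 and 50.8 CPM in any other fish. Apart from pro139C and pro139A, probiotic fish held 4.77 to 7.59 CPM of ela2, inside the antibiotic range of 4.34 to 27.9 CPM. Of 14 skeletal muscle genes 10 were higher (median 0.65, camera adjusted p = 0.207, and adjusted p = 0.940 with an estimated correlation). A member of the latter, atp2a1, passed when adjusted over the list alone (3.48 ± 2.62 against 0.629 ± 0.592 CPM).

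No single gene passed edgeR between the treatments (0 of 30221). At an unadjusted p under 0.05 there were 1827 genes, 1105 of them higher in antibiotic fish, where 1511 were expected by chance. In fits of only these 2 groups, 14 of 50 splits of the libraries, the real one included, had as many as the real division. DESeq2 called 23 genes, 13 of them higher, and limma-voom called 0. LOC112249934 had the smallest p, at 35.9 ± 5.16 CPM in antibiotic fish (SD, n = 5) and 20.6 ± 1.98 CPM in probiotic fish (SD, n = 6), higher in 5 of 5 fish (log2 fold change 0.80 ± 0.14 SE, edgeR adjusted p = 0.572, DESeq2 adjusted p = 0.00271). The kinase gene wee2 averaged 9.77 ± 1.41 against 4.23 ± 1.31 CPM, above all probiotic fish in 5 of 5 (log2 fold change 1.21 ± 0.24 SE, edgeR adjusted p = 0.653). The focal adhesion gene tes averaged 23.4 ± 6.42 against 50.5 ± 18.9 CPM, below all probiotic fish in 4 of 5. LOC112234117, LOC112220311, LOC112248188, LOC112226288, LOC112252883 and LOC112227924 had log2 fold changes of 3.90, 1.07, 5.75, 0.52, 0.74 and 7.60, and LOC112247759 one of -0.99. LOC112227924 reached 783 CPM in antibiotic fish abx91A. In 113 genes (0.374%) the groups did not overlap, where chance gives 0.433%. Without those 4 fish camera no longer called the heat shock (median -0.23, adjusted p = 0.261), mitochondrial ribosome (-0.018, 0.876) or cytosolic ribosomal list (0.077, 0.0809), whereas with the plate column these medians grew to -0.56, -0.27 and 0.22 (3.44e-06, 3.21e-07 and 5.07e-06). With the smooth muscle score as a covariate the mitochondrial ribosome median was -0.032 (camera adjusted p = 0.487), the heat shock median shrank to -0.16 (0.0018), and the cytosolic ribosomal call ended at 0.079 (0.0812), as it did at 0.041 without ctl12A and pro139A (0.352).

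Antibiotic and probiotic responses against the same controls were then set side by side. Across 30221 genes the log2 fold changes had a Pearson correlation of 0.504, where simulated unchanged groups against these controls gave 0.476 ± 0.00761 (SD, 20 simulations). That SD holds no spread between fish. The jackknife SE over fish was 0.218, and with each fish left out the correlation ranged from 0.359 to 0.593, so the observed value was not apart from the simulated one. The covariance was 0.0812, against 0.0670 simulated, a difference of 0.0142. With the 6 controls split 3 and 3 so that no control served both comparisons, the mean correlation over 20 splits was 0.0994, with a range from -0.107 to 0.224. Genes had one sign in both comparisons in 70.2% of cases, against 65.9% simulated. At an unadjusted p under 0.05 in both, 252 genes were higher and 208 lower. Independent lists of the sizes used would share 45.3 and 32.4, and the simulation shared 174 and 117. In 4 genes the signs were opposite, where the simulation gave 1.9 on average. The sizes of the edgeR lists given above do not yield these independent values, so the counts are not to be read as overlaps of those lists. The simulated shares carry no spread between fish either, so the excess over them was not tested.

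Fish that share a title number were compared within each group, since a number may mark a common tank, which the labels do not say. Between the 2 numbers of the control group edgeR called 0 genes, with 1859 at an unadjusted p under 0.05, and DESeq2 called 16. Between those of the antibiotic group edgeR called 0, with 2162 at that level, and DESeq2 called 63. Between those of the probiotic group edgeR called 0, with 2887 at that level, and DESeq2 called 96. Fish of one title number correlated at a mean of 0.952, against 0.949 for fish of the same group and another number (one-sided permutation p = 0.0569). Most pancreas genes separated the 2 numbers of the control group, as given below.

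Genes typical of other organs were high in some fish. Antibiotic fish abx67C exceeded all controls in 13 of 18 liver genes, among them fgg at 22.1 CPM (highest control 2.34), and probiotic fish pro139B also did so in 13, abx67B in 11 and pro115A in 10. Probiotic fish pro139C held 240 CPM of the pancreatic elastase gene ela2 and 295 CPM of cpb1, a carboxypeptidase, against at most 43.8 and 50.8 CPM in any other fish. Antibiotic fish abx91B held 4.10 CPM of the egg coat gene zpd, against at most 0.201 CPM elsewhere.

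**Figure D4:**
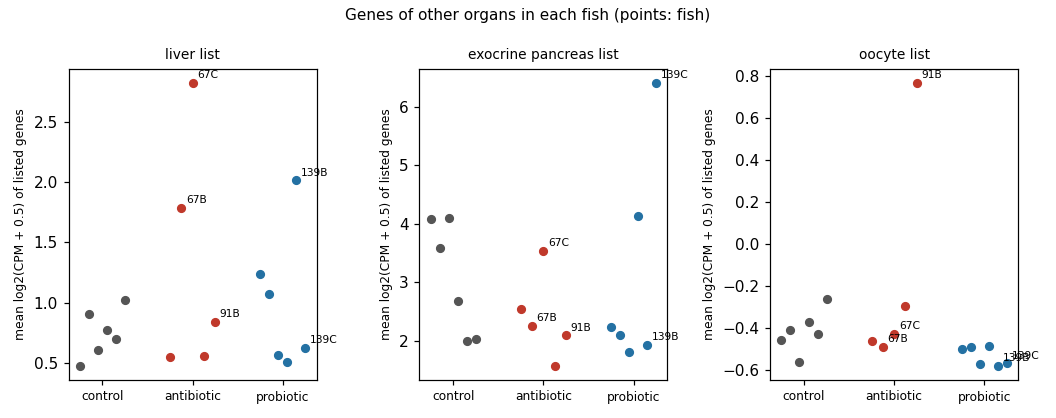
Mean log2(CPM + 0.5) of liver, exocrine pancreas and oocyte genes in each fish, with points for fish and control, antibiotic and probiotic fish side by side. Fish abx67C and pro139B stand highest in liver genes, pro139C in pancreas genes and abx91B in oocyte genes.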

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

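The explanations weighed in this part were all tested after the results were seen, and the list of oocyte genes was chosen then. Genes of another organ stood out in some fish, and in antibiotic fish abx67C 13 of 18 liver genes exceeded all controls, as did 13 in pro139B, 11 in abx67B and 10 in pro115A. An antibiotic effect in every fish is not supported, since only 2 of 5 antibiotic fish had a liver score above all controls and 3 probiotic fish had one. In pro139C 6 of 6 pancreatic enzyme genes, and in abx91B 13 of 17 oocyte genes that had at least 10 reads, exceeded every other fish. These counts measure the pattern itself, so liver, pancreas or ovary tissue carried into the samples stays open and was not tested by them. No biological explanation was tested for the pancreas and oocyte genes, as the design gives none.

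A smaller share of muscle layer could account for the lists that were higher in probiotic fish. With the smooth muscle score as a covariate the medians of the cell cycle, sterol, mitochondrial ribosome and heat shock lists kept 15.5% of their size on average (-5.46, 2.86, 37.7 and 26.8%). The mitochondrial ribosome and heat shock lists still passed camera (adjusted p = 0.0241 each). A score computed from the same fish can also take up a true treatment effect, so the test does not separate the 2.

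The endocytic and lysosomal list did not lose its shift with the smooth muscle score as a covariate. Its median stayed at -0.14 in antibiotic fish (camera adjusted p = 0.00587) and moved to -0.19 in probiotic fish (1.70e-05). The bound for this test was reset after a first result near the earlier bound, and it also required a camera call at the preset correlation. A part played by the muscle layer is therefore not excluded by it. The call moved both ways: without abx67C, abx91B, pro139B and pro139C it ended in antibiotic fish (median -0.084, camera adjusted p = 0.157) and grew in probiotic fish (-0.29, 0.000132), with the plate column it grew in antibiotic fish (-0.27, 8.66e-06) and ended in probiotic fish (-0.12, 0.0782), and without ctl12A and pro139A it ended in antibiotic fish (-0.11, 0.143). With an estimated correlation the list was not called (adjusted p = 0.857 and 0.887 with an estimated correlation), and a treatment effect on lysosomal enterocytes stays untested beyond this.

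Dixon's criterion for a fish far from the rest of its group picked 13 of 186 groups, and it picks about 1 in 20 groups by chance. Among list scores it picked 2 of 105 where 5.25 were expected. For the 25 genes named for the smallest p in a comparison it picked 11 of 75, where the same rate gives 3.75. These genes were chosen on the same values, so that rate need not hold for them. The endocytic and lysosomal score of abx91B was 7.30 (nearest fish 7.46), and the stem cell and wnt score of pro139C was 0.14 (nearest 0.77). In log2 CPM, ubr4 stood at 0.091 in abx91A (nearest 2.63), LOC112226994 at 0.26 in abx67C (nearest 0.49) and LOC112242158 at 7.32 in ctl12A (nearest 7.91). The gene frmd4bb stood at 4.91 in abx67B (nearest 5.42) and 3.76 in pro115C (nearest 4.58), and wee2 at 0.80 in pro115C (nearest 2.09). LOC112249934 stood at 4.76 in abx91A (nearest 5.20) and 4.61 in pro139B (nearest 4.38), and LOC112226288 at 5.94 in ctl35B (nearest 5.6). LOC112227924 stood at 9.61 in abx91A (nearest 0.68) and at -1.53 in pro115B (nearest -0.45).

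The direct comparison of the treatments is a test of the difference between their effects. It differed by a median log2 of 0.42 for interferon genes, -0.31 for heat shock, -0.11 for the mitochondrial ribosome, 0.10 for cytosolic ribosomal proteins and 0.41 for immediate early genes, each at the preset correlation only.

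Signals outside the comparisons were of 2 kinds. In abx91B 44 genes had at least 1 CPM and under 0.15 CPM in every other fish, where no other fish had over 9 such genes. The unnamed mitochondrial entry held 0.523% of counts in abx67C and 0.504% in pro115B, against at most 0.422% in controls.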

How the results depend on the processing

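Most of the alternatives were planned. Leaving out 4 libraries high in genes of other organs (abx67C, abx91B, pro139B, pro139C), leaving out ctl12A and pro139A, the plate column, and each fish in turn for title numbers and the shared response were chosen after values were seen. Of 608 values of the 19 called lists, 483 kept their side of the threshold, 122 lost it with the same sign and 3 lost it with a median of the other sign. These 3, all in probiotic versus control, were the cell cycle at -0.029 and smooth muscle at 0.014 with the smooth muscle covariate, and the cell cycle at -0.039 with 1 surrogate variable. Of 3831 values of named genes, 3788 stayed, 43 passed under an alternative (39 of them in DESeq2) and 0 were called in the other direction. Genes called became 26, 34 and 23 in DESeq2 (antibiotic versus control, probiotic versus control, antibiotic versus probiotic), 1 for probiotic versus control with only the 2 groups in the fit, and 1 for antibiotic versus control with the plate column. Lists called for antibiotic versus control became 3 with quality weights, 10 with counts summed per title number, 3 without ctl12A and pro139A and 8 with the plate column. For antibiotic versus probiotic they became 9 when summed per title number, 3 with the smooth muscle covariate, 3 without the 4 libraries and 11 with the plate column. With an estimated correlation 0, 0 and 0 lists were called, and with fry 0, 0 and 0. Between title numbers DESeq2 called 16 genes in controls, 63 in antibiotic and 96 in probiotic fish. The shared response was 0.0994 with controls split. In each case the cause was not tested. No paired analysis was possible because no title number occurs in 2 groups. Camera with the title number as a block was not run.

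With each fish left out in turn, genes called ranged 0–0 for antibiotic versus control, 0–1 for probiotic versus control (1 without ctl12A, 1 without abx67B) and 0–0 for antibiotic versus probiotic. Lists called ranged 2–8 (2 without ctl12A, 8 without abx67A, 8 without abx67C), 6–11 and 5–11 (8 without pro115A, 11 without pro115B). Between title numbers genes ranged 0–0 in controls, 0–56 in antibiotic fish (1 without abx91A, 56 without abx91B, each leaving 1 library under its title number, assumed to vary like the other groups) and 0–29 in probiotic fish (1 without pro115B, 1 without pro115C, 29 without pro139B). The shared response ranged 0.359–0.593, with a jackknife SE of 0.218. The cause was not tested.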

Other observations

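In this part the split tests of the 3 comparisons were chosen only after a first run of them had been seen, the tests of the pair ctl12A and pro139A after its correlation was seen, and the splits by title number were planned. Junction and nerve genes showed small shifts that passed no test. The tight and adherens junction score, the mean log2 CPM of claudins, occludin and other genes that seal the epithelium, was 2.73 ± 0.18 in antibiotic fish (SD, n = 5), 2.45 ± 0.22 in controls (SD, n = 6) and 2.49 ± 0.13 in probiotic fish (SD, n = 6). The exact permutation p was 0.0563 against controls and 0.0346 against probiotic fish, and adjusted over 35 lists 0.669 and 0.825. Enteric neuron and glia genes were lower in 10 of 11 members in antibiotic fish (median log2 fold change -0.28, camera adjusted p = 0.0894, and adjusted p = 0.857 with an estimated correlation). They were lower in 9 of 11 members in probiotic fish (median -0.43, camera adjusted p = 0.0962, and adjusted p = 0.887 with an estimated correlation).

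Libraries of 2 groups were divided at random into groups of the same sizes, with the real division counted among the splits, and fits held only those 2 groups. For antibiotic versus control, 10 of 50 splits had as many genes at an unadjusted p under 0.05 as the real 1855 (highest other 8317). As many lists as the real 6 were called in 44 (highest other 19), and as many DESeq2 genes as the real 42 in 5 of 25 (highest other 4734). Chance was not excluded for these. Genes called by edgeR give no test here, since the real count was 0 and all 50 of 50 splits reach it (highest other 2485). The split with 2485 calls set ctl12B, ctl35A, ctl35B, ctl35C and abx91A against the others. It was the highest of those drawn, and whether it reflects a structure of the samples was not tested.

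For probiotic versus control, 5 of 50 splits had as many genes at an unadjusted p under 0.05 as the real 2807 (highest other 3747), 30 called as many lists as the real 9 (highest other 16), and 7 of 25 called as many DESeq2 genes as the real 30 (highest other 113). Chance was not excluded for these. In edgeR 2 of 50 called as many genes as the real 1, and the highest other was 1. Adjusted over the split tests that share is 0.40, so chance was not excluded for it either. For antibiotic versus probiotic, 14 of 50 splits had as many unadjusted genes as the real 1532 (highest other 4063), 45 called as many lists as the real 5 (highest other 16), and 8 of 25 as many DESeq2 genes as the real 37 (highest other 850). Chance was not excluded for these, and edgeR calls again give no test, with a real count of 0 that 50 of 50 splits reach (highest other 2).

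Fish of the 2 title numbers of a group were also compared with all 10 splits of that group's libraries, in fits of those libraries alone, so the counts differ from those of the fit of all 17. In controls 2 of 10 splits reached the real 2323 genes at an unadjusted p under 0.05 (highest other 4071), and in probiotic fish 2 of 10 reached the real 2437 (highest other 4336). These splits are too few for a share under 0.05.

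Control ctl12A and probiotic pro139A had the highest correlation of all 136 pairs, at 0.982, and the next was 0.968. They lie in neighbouring wells of an index column by their library titles. The median chi-square per gene between them was 4.61, where a library deposited under both names would give under 1. Between them 29 genes of at least 5 CPM in one were under 5% of that level in the other, which argues against mixing well above 5%. Of these, 22 were high in pro139A and 7 in ctl12A, so fewer genes bear on reads of ctl12A in pro139A. Counting noise can put a gene under that level when mixing is near 5%, so mixing near or below 5% is not excluded. What makes the pair alike was not found, and no biological explanation was tested, as the design gives none.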
